A study of Mus musculus with 2 samples.

How the data were processed

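Per the labels' protocols, total RNA was extracted from flow-sorted spleen DC of 2 samples, and 150 ng per sample was labelled with biotin by standard Affymetrix procedures for hybridisation to a mouse gene array. The deposited values are log2 intensities per probe set. The submitters' processing notes name RMA, which corrects background, quantile normalizes the arrays and summarises probes into probe sets, and the oligo package, whose version is not given in the sources used here. Which arrays were normalized together is also not given; the series' design text speaks of a joint re-processing with untreated and polyI:C arrays, and that joint table is not used here. The sorted values of the 2 columns differed by at most 0.058, as quantile normalization would leave them, so a global difference in RNA amount between samples is removed from these values and cannot be seen. RMA also compresses differences near background, so folds of dim genes are understated.

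The table holds 35556 probe sets with values from 3.52 to 14.16 in replicate 1 and from 3.58 to 14.14 in replicate 2, and medians of 6.59 and 6.62. An annotation of the platform named 1 gene for 21789 probe sets and several genes for 1621, and left 12146 unnamed here. Of the 1-gene probe sets, 21698 were matched by Entrez identifier to a RefSeq gene table (assembly GRCm38.p6), and no symbol needed updating. No build is given for the array values, and no coordinates are given. A gene with several probe sets (999 of 19938 genes) was given by their mean and taken as above background if any of them was; the probe sets disagreed on the call for 192 genes. Probe sets naming several genes entered no list.

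Both samples carry the same treatment label and form 1 group, with replicate numbers from the titles. No sample of another condition was among them, so no test between groups was possible and none is reported. Before the data were examined, 25 gene lists, the rules and the alternatives were fixed: 11 lists of DC and immune programmes, 3 for RNA quality and stress, and 11 of markers of other cell types. Of their 504 entries, 449 were measured through a 1-gene probe set, 3 of them under a newer symbol; of the other 55, 24 are on probe sets naming several genes and the rest are not analysed here. Some genes are in more than 1 list, for example 6 of the 31 measured cytokine and chemokine genes and 4 of the 14 cDC2 markers. An array's background floor was the 95th percentile of its olfactory receptor probe sets. The number of list members above background was placed among 10000 random lists of the same size drawn from all measured genes, with tied lists counted at mid-rank. The difference, replicate 1 minus replicate 2, was summarised per list by the median over members above background in at least 1 array, for lists with at least 5 such members. It was placed among 10000 random lists matched gene by gene on mean level in 20 bins, with a 95% bootstrap interval from 10000 draws of members. The interval describes spread over the members, which may vary together, and not over samples. The platelet list had too few members for a difference.

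The genes named were taken from the first 5 measured members of each list, list members whose arrays differed by at least 1 log2 unit, up to 5 members above background of each other-cell list, and the 10 largest differences in each direction of at least 1. Not all of these are printed. The text says where a gene was named after its value was seen; values of further list members serve as examples. Alternatives were a 99th percentile floor, a floor from 297 probe sets of vomeronasal and taste receptor, keratin-associated and beta-defensin genes, the mean of the arrays against the mean floor, each array alone, the highest probe set per gene, quantile normalization of the 2 arrays, median centring, removal of a loess trend of difference on level (span 0.3), no filter on dim genes, a 1.5-fold threshold and unmatched random lists. Lists reduced to members held by no other list were added after the data were seen, as were 5 second lists (immediate early, heat shock, type I interferon response, NF-κB target and erythroid genes; 115 of 123 entries measured), written after the values of the first lists were known and before their own were. The scripts were tested on simulated differences over 12621 genes: all genes shifted by 1.5 log2 units and none of those shifted by 0.5 or left unshifted passed the threshold of 1, and a list of 25 genes shifted by 0.25 was recovered at 0.27. The simulated noise was normally distributed and independent between genes, so this checks the code and gives no rate of false calls for these arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.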

Results

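Transcript levels were measured on arrays in XCR1+ dendritic cells (DC) sorted from mouse spleen 12 hours after intravenous injection of 20 µg of STAg, the name used in this field for a soluble extract of Toxoplasma gondii tachyzoites. XCR1+ DC, also called type 1 conventional DC (cDC1), are the subset specialised in presenting antigen to CD8 T cells. The 2 samples form a single group, replicates 1 and 2, and were gated as lineage-negative cells with high CD11c, CD8α and no or low CD317. The study set these cells beside XCR1+ DC from untreated mice and from mice given polyI:C. Those arrays were not analysed here, so no level below is a response to STAg, and no test between conditions was made. Of the 35556 probe sets, 21789 name a single gene and measure 19938 genes. A gene was taken as above background when a probe set of it exceeded, in both arrays, the 95th percentile of 1035 olfactory receptor probe sets, which was 5.99 in replicate 1 and 6.04 in replicate 2 on the log2 scale. By this rule 12281 genes, or 61.6%, were above background. Levels are log2 values given as mean ± SD (n = 2). The precision is limited by the number of arrays, and because probes differ in their response, a level is set only against background and never against the level of another gene.

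The sorted cells carried the transcripts of the cDC1 lineage and of mature DC without exception among the genes measured. All 23 measured genes of the cDC1 identity list were above background, among them the chemokine receptor gene Xcr1 (11.01 ± 0.035), the dead-cell receptor gene Clec9a (10.51 ± 0.018), the lineage transcription factor genes Batf3 (10.54 ± 0.10) and Irf8 (12.77 ± 0.075), and Cd8a (11.05 ± 0.00071), whose product was part of the gate. All 28 measured genes of the DC maturation list were also above background. They included Ccr7, the receptor that guides DC towards T cell zones, at 13.51 ± 0.021, and the costimulatory genes Cd40 at 12.59 ± 0.034, Cd80 at 12.29 ± 0.15 and Cd86 at 10.82 ± 0.15. The Cd80 value is the mean of 2 probe sets, at 12.82 and 11.97 in replicate 1. Cd83, a classical maturation marker, measured 12.55 ± 0.054. Random lists of 23 and of 28 genes had medians of 14 and 17 members above background, and none of the 10000 drawn for either list held as many as observed. These percentiles describe the 2 arrays and are not tests, since genes are not replicates. The random lists were drawn from all measured genes, including the olfactory receptor genes, which mostly lie below the floor by its definition. The ribosomal protein and respiratory chain lists also reached percentile 100. Exceeding random lists is therefore not particular to cDC1 identity or maturation genes.

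The cytokine list was detected in part. Il12b, which encodes the p40 subunit of interleukin 12, measured 13.07 ± 0.097, whereas Il12a, which encodes the partner subunit p35, was not above background in either array (5.43 ± 0.020). Il6 (10.53 ± 0.019), Il1b (9.24 ± 0.17) and Tnf (11.51 ± 0.60) were above background. In all, 23 of the 31 measured cytokine and chemokine genes passed the floor, the 92.3rd percentile of random lists. The other 8, listed here after their values were seen, were Il12a, Il1a, Il10, Il23a, Ifnb1, Cxcl2, Tnfsf4 and Csf2. The SD of Tnf was larger than that of Il6 or Il1b, and Ccl3 and Ccl4 from the same list had SDs of 2.21 and 0.75. In the same arrays the stress and immediate early list was higher in replicate 2 by a median of 1.73-fold. Of the Toll-like receptor pathway list, 20 of 22 measured genes were above background (percentile 99.8), among them Tlr12, a sensor of the Toxoplasma protein profilin (7.49 ± 0.058), the adaptor gene Myd88 (10.80 ± 0.081), the double-stranded RNA sensor gene Tlr3 (9.25 ± 0.017), Tlr1 (9.08 ± 0.13) and Unc93b1, which carries endosomal receptors to their compartment (11.33 ± 0.066). Tlr4 and Tlr8, named because they were the only 2 of the list not above background, measured 5.05 ± 0.035 and 4.65 ± 0.045. Tlr11 was not analysed here.

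Genes of both interferon programmes were present in these cells. All 26 measured type I interferon response genes were above background, including the antiviral effector genes Ifit1 (10.43 ± 0.32), Ifit2 (10.03 ± 0.24), Ifit3 (9.90 ± 0.16), Mx1 (10.56 ± 0.16) and Rsad2 (9.43 ± 0.40). Of the interferon-gamma response list, 18 of 19 were above background, with the chemokine gene Cxcl9 at 13.02 ± 0.028, the immunity-related GTPase gene Irgm1 at 11.78 ± 0.12, the guanylate-binding protein genes Gbp3 at 10.14 ± 0.066 and Gbp4 at 12.52 ± 0.016, and the transcription factor gene Irf1 at 10.56 ± 0.044. The Irf1 value is the mean of 2 probe sets far apart, at 12.60 and 8.59 in replicate 1, both above background, and describes neither. The 19th, Serping1, was below it and is named after its value was seen. Antigen presentation genes were above background throughout, 16 of 16 for the MHC class I pathway and 13 of 13 for MHC class II. B2m, the light chain of class I molecules, measured 13.35 ± 0.018, the peptide transporter genes Tap1 and Tap2 12.42 ± 0.010 and 11.25 ± 0.066, the immunoproteasome gene Psmb8 11.97 ± 0.00076 and the peptide-loading gene Tapbp 12.36 ± 0.13. For class II, H2-Ab1 measured 12.95 ± 0.11, H2-Aa 12.99 ± 0.080, the invariant chain gene Cd74 13.04 ± 0.031, the class II transactivator gene Ciita 10.67 ± 0.081 and H2-DMa 11.51 ± 0.20.

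Cell cycle transcripts were detected in full, 27 of 27 measured genes, with the proliferation marker Mki67 at 10.39 ± 0.12, the mitotic kinase gene Cdk1 at 10.07 ± 0.061, Ccna2 at 10.01 ± 0.075 and Birc5 at 8.05 ± 0.082. Top2a rested on 2 probe sets that disagreed, one at 10.28 in replicate 1 and 10.23 in replicate 2 and the other below background in both, so its mean has no clear meaning. Of the sterol list, 19 of 21 genes were above background, including the synthesis genes Hmgcs1 (10.22 ± 0.00034), Sqle (9.34 ± 0.079) and Idi1 (10.47 ± 0.18) and the oxysterol receptor gene Nr1h3 (6.67 ± 0.14). The cholesterol efflux gene Abca1 was not (5.77 ± 0.016). All 13 measured apoptosis and survival genes were above background, including the survival genes Bcl2 (8.18 ± 0.093), Bcl2l1 (8.37 ± 0.27) and Mcl1 (11.99 ± 0.00013) and the death-promoting genes Bcl2l11 (11.23 ± 0.043) and Bak1 (10.45 ± 0.018). The ribosomal protein and respiratory chain lists, used as references for RNA quality, were above background in 19 of 19 and 24 of 24 genes, for example Rplp0 at 13.31 ± 0.0044, Rps3 at 11.65 ± 0.0062, Atp5b at 12.83 ± 0.013 and Cox4i1 at 10.21 ± 0.017.

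Fewer markers of NK cells and neutrophils than of the other DC subsets were above background. Of the NK cell list 6 of 16 genes were above background (percentile 2.84), and the natural cytotoxicity receptor gene Ncr1 (4.72 ± 0.044), Klrb1c (4.20 ± 0.012), Eomes (5.83 ± 0.071), Gzma (4.87 ± 0.033) and Gzmb (5.45 ± 0.21) were not. Those above it included Ccl5 (13.55 ± 0.0011), which the cytokine list also holds, Klrk1 (9.85 ± 0.11), Prf1 (6.64 ± 0.0096), Nkg7 (6.35 ± 0.054) and Xcl1 (6.25 ± 0.029). Among neutrophil markers 7 of 17 passed (percentile 4.76), none of them S100a8 (5.77 ± 0.050), S100a9 (5.88 ± 0.079), Csf3r (5.55 ± 0.0018) or Cxcr2 (4.72 ± 0.068). Those that passed included Ngp (6.29 ± 0.30), Camp (6.40 ± 0.098), Mpo (6.21 ± 0.14), Elane (6.19 ± 0.068) and Prtn3 (6.49 ± 0.013). B cell markers passed in 8 of 15 genes, with Ms4a1 at 8.05 ± 0.16, Cd79b at 9.37 ± 0.26, Pax5 at 6.28 ± 0.021, Blk at 6.22 ± 0.12 and Cd22 at 6.38 ± 0.018 above background and Cd79a at 4.59 ± 0.17 below it. T cell markers passed in 10 of 16, with Cd3e at 6.61 ± 0.092, Cd5 at 7.42 ± 0.11, Cd6 at 6.39 ± 0.20, Thy1 at 6.48 ± 0.087 and Cd247 at 6.50 ± 0.030. The others included Il7r at 10.33 ± 0.086, Cd8b1 at 9.76 ± 0.048 and Ubash3a at 7.82 ± 0.21, named after their values were seen. Cd3d, at 5.01 in both arrays, and Cd3g at 4.54 ± 0.057 were below background.

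The cDC2 list was above background in 12 of 14 genes, with Sirpa at 10.42 ± 0.14, Irf4 at 9.36 ± 0.19, Esam at 8.49 ± 0.16, Cd4 at 7.50 ± 0.13 and the integrin gene Itgam at 6.17 ± 0.0085, while Clec4a4 was not (4.69 ± 0.034). The plasmacytoid DC list passed in 11 of 12 genes, with Siglech at 7.39 ± 0.17, Bst2, which encodes the CD317 used in the gate, at 10.22 ± 0.10, Tcf4 at 9.98 ± 0.0055, Ccr9 at 7.64 ± 0.062 and Ly6d at 7.52 ± 0.0080. Without an array of unstimulated or of other cells, these levels cannot be divided between XCR1+ DC and cells carried over in the sort. Monocyte and macrophage markers passed in 11 of 18 genes, among them Lyz2 (8.86 ± 0.47), Csf1r (7.62 ± 0.32), Ccr2 (6.30 ± 0.29), Fcgr1 (6.53 ± 0.043) and Spic (9.10 ± 0.032), and not Cd14 (5.43 ± 0.12) or Adgre1 (5.20 ± 0.12). Plasma cell markers passed in 8 of 10 genes, for example Xbp1 (10.58 ± 0.045), Prdm1 (7.26 ± 0.11), Jchain (6.59 ± 0.19) and Sdc1 (6.66 ± 0.061). Erythroid markers passed in 4 of 10 (Slc4a1 at 6.90 ± 0.49, Car1 at 6.80 ± 0.41, Car2 at 9.90 ± 0.12 and Tspan33 at 10.26 ± 0.046). Epb42 (5.51 ± 0.063) and Rhag (4.58 ± 0.026) did not, and Klf1 (5.94 ± 0.087) passed only in replicate 1. Platelet markers passed in 4 of 6 (for example Itga2b at 7.03 ± 0.021, with Pf4 at 4.89 ± 0.0094 below). Stromal and endothelial markers passed in 10 of 16, for example Col1a1 at 7.65 ± 0.026, Pecam1 at 7.23 ± 0.18 and, named after its value was seen, Kdr at 11.34 ± 0.0061. With the 99th percentile of the olfactory receptors as the floor, the neutrophil count became 0 and the B cell and NK cell counts 2 each, whereas the cDC2 and plasmacytoid DC counts were 10 and 11.

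**Figure D1:**
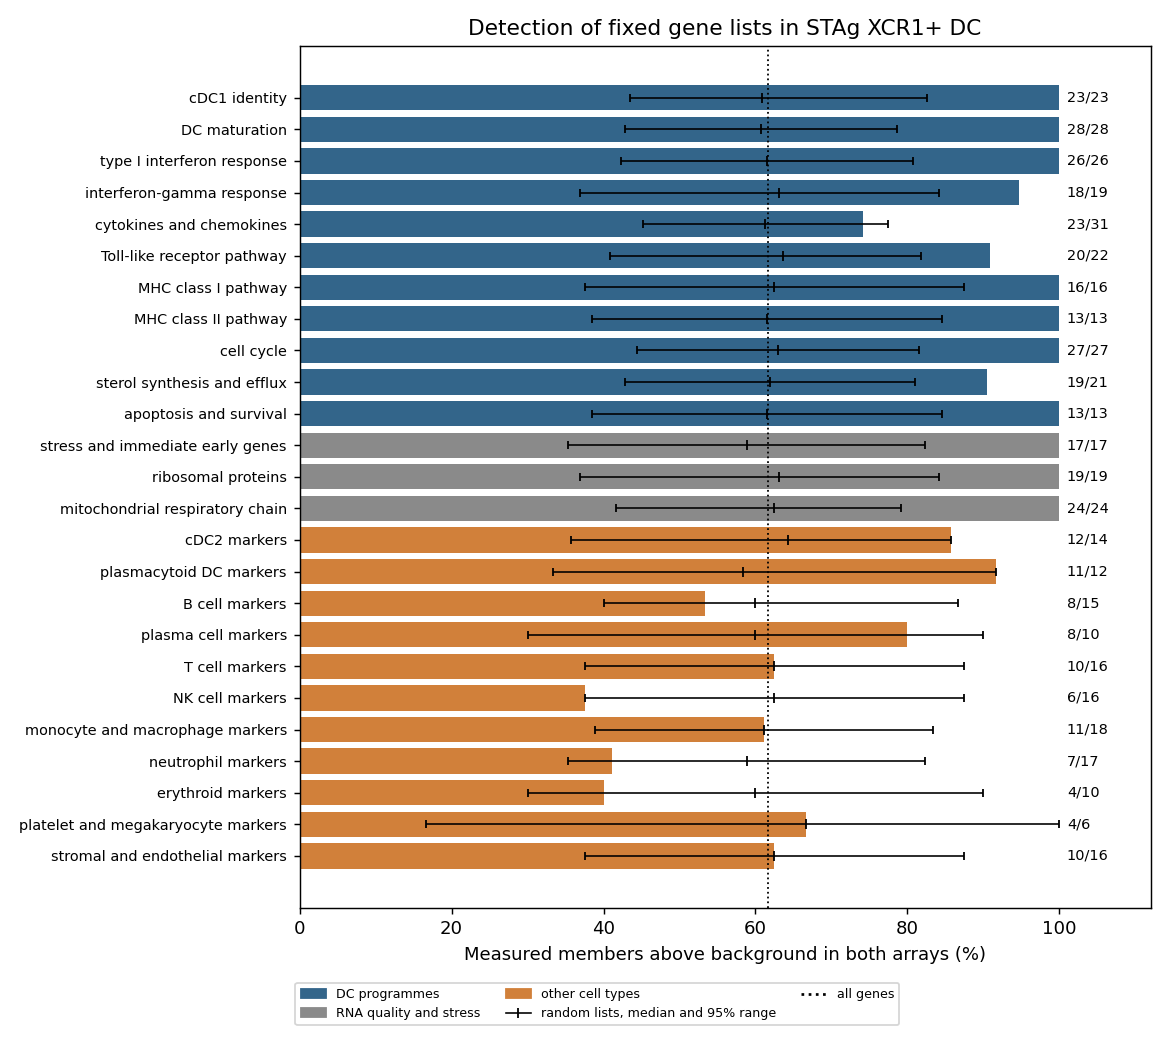
Bars give the percentage of measured members of each gene list that were above background in both arrays, with the counts at the right, and black markers give the median and 95% range of 10000 random lists of the same size. The lists for cDC1 identity (23 of 23), DC maturation (28 of 28) and type I interferon response (26 of 26) lie beyond their random ranges. Those for NK cells (6 of 16), erythroid cells (4 of 10), neutrophils (7 of 17), B cells (8 of 15) and monocytes and macrophages (11 of 18) lie below the dotted line for all genes (61.6%), but within their random ranges.

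The second question the files allow is how well the replicates match, since each SD above is the spread between these 2 arrays. That spread is not the full error of a level, because the labels do not say whether the replicates are separate mice. Over the 12281 genes above background the differences between the arrays had an SD of 0.156 log2 units, which corresponds to a typical SD of 0.11 for a single gene, and 99.1% of these genes differed by less than 0.5. Pearson's r across these genes, which are not independent replicates, was 0.996. Of the 12621 genes above background in at least 1 array, 21 differed by at least 1 log2 unit, a 2-fold difference, and 20 of the 21 were higher in replicate 2. This imbalance holds for probe sets naming a single gene: by the same threshold, 57 of the probe sets unnamed here were higher in replicate 1 and 20 in replicate 2, and 7 and 8 of those naming several genes. With 1 array on each side these differences have no replicate check and no p-value.

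Of the 20 genes higher in replicate 2, 6 belong to the stress and immediate early list and 2 to the cytokine list. Hspb1, a small heat shock protein gene, differed by the most, 12.8-fold, measuring 6.77 in replicate 1 and 10.45 in replicate 2, with the same difference in both of its probe sets, which are therefore not independent. The chemokine gene Ccl3 was 8.74-fold higher in replicate 2 (9.11 against 12.23), and Ccl4 2.09-fold (6.35 against 7.41). The heat shock cochaperone genes Dnajb4 and Dnajb1 were 4.56-fold and 2.26-fold higher, and Hspa1a 2.36-fold. Among immediate early genes, Egr1 was 4.40-fold, Fosb 3.23-fold, Fos 3.00-fold, Nr4a1 2.31-fold and Jun 2.20-fold higher. Rhob was 3.84-fold, Lilr4b 2.89-fold and Fam71a 2.81-fold higher. The small nucleolar RNA gene Snord52 was below background in replicate 1 and, against the floor of that array, at least 2.47-fold higher in replicate 2. The 1 gene higher in replicate 1 was Alas2, which encodes the erythroid enzyme of haem synthesis, at 7.27 in replicate 1 and below background in replicate 2, at least 2.35-fold higher against the floor.

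**Figure D2:**
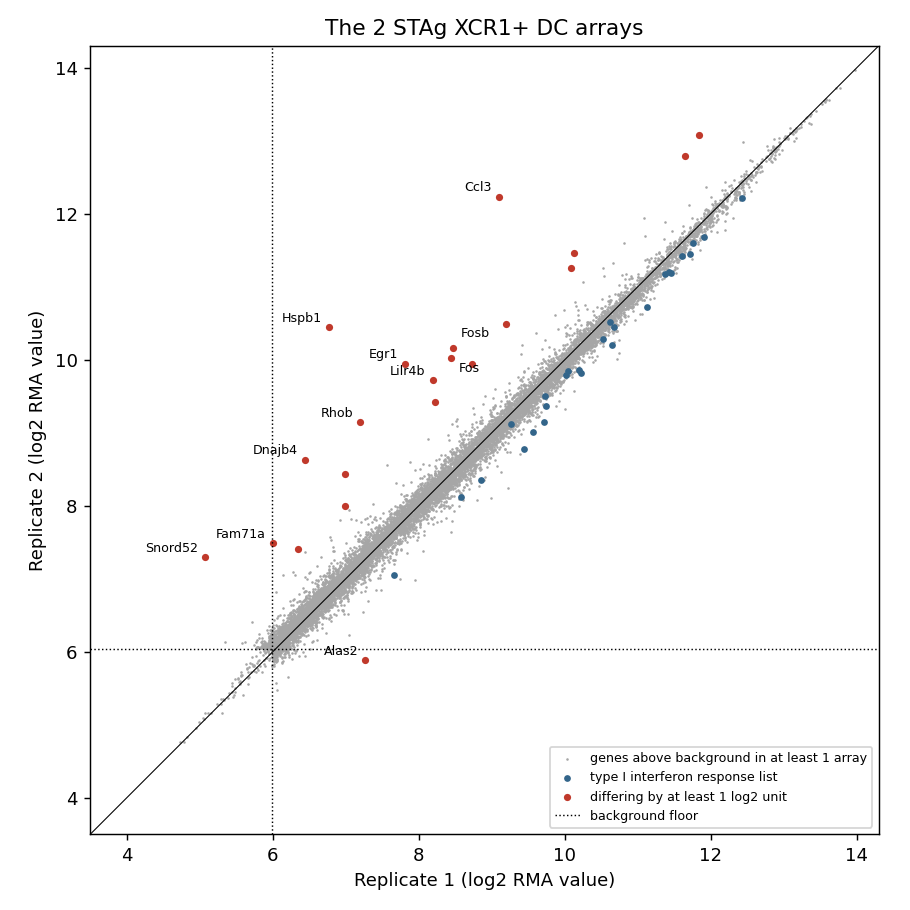
Each point is a gene above background in at least 1 array, placed by its log2 RMA value in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with dotted lines at the background floors of 5.99 and 6.04. The 21 genes that differed by at least 1 log2 unit are red, 20 of them above the diagonal, and the 26 type I interferon response genes are blue and all lie below it.

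By gene list, the widest difference was in the stress and immediate early list, for which 16 of 17 genes were higher in replicate 2, with a median of 1.73-fold (-0.79 in log2 units, replicate 1 minus replicate 2). The type I interferon response list differed the other way: all 26 genes were higher in replicate 1, by a median of 1.19-fold (0.25), with Ifit1 at 10.65 and 10.20 in replicates 1 and 2. Both medians lay outside all 10000 random lists matched on level. The cell cycle list was higher in replicate 2 in 25 of 27 genes (median -0.11) and the MHC class II list in 11 of 13 (median -0.12), again below all random lists, although each corresponds to 1.08-fold. The interferon-gamma response list had a median of 0.077 (percentile 98.6), with 13 of 18 genes higher in replicate 1, and lay inside the central 95% of random lists when the loess trend was removed (percentile 97.46). The lists for cDC1 identity (0.013), DC maturation (0.062), MHC class I (0.040), ribosomal proteins (-0.0090) and the respiratory chain (0.014) had medians within the range of random lists. With the loess trend removed, those for cDC1 identity and the respiratory chain were -0.020 and -0.010. In the DC maturation list, 25 of 28 genes were higher in replicate 1 (percentile 96.8), and the list lay above the central 95% of random lists when the arrays were quantile normalized to each other (percentile 97.78).

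Some marker lists of other cells also lay outside the range of random lists. Neutrophil (-0.14, 7 of 7 genes higher in replicate 2), T cell (-0.12) and cDC2 markers (-0.10) were below the central 95% of random lists. The bootstrap intervals of the T cell (-0.15 to 0.068) and cDC2 (-0.25 to 0.11) lists included 0. The interval of the neutrophil list did not (-0.23 to -0.096). Its 7 genes had mean levels of 6.19 to 6.49, close to the floors of 5.99 and 6.04. The monocyte and macrophage list had a median of -0.077 (percentile 9.42), although Lyz2 and Csf1r differed by -0.67 and -0.46. The cDC2 list lay inside the random range when the loess trend was removed (percentile 3.56) or dim genes were not filtered out (percentile 7.64). Erythroid markers had a median of 0.094 (percentile 97.6), with a bootstrap interval of -0.38 to 1.04 that included 0. They lay inside the random range when the loess trend was removed (percentile 96.7), with the highest probe set per gene (97.28) or with unmatched random lists (95.66). The 4 probe sets whose listed genes are all globin genes, which entered no list and were chosen after their values were seen, were 8.49-fold to 10.5-fold higher in replicate 1. In all, 9 of the 24 lists with at least 5 usable genes lay outside the central 95% of random lists. If genes varied independently, 1.2 would be expected. Some lists share genes and members of a list may vary together, so this comparison is not a test. Nothing in the labels says whether the replicates came from separate mice or pools, so their differences measure only the spread between these samples, which may be technical.

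**Figure D3:**
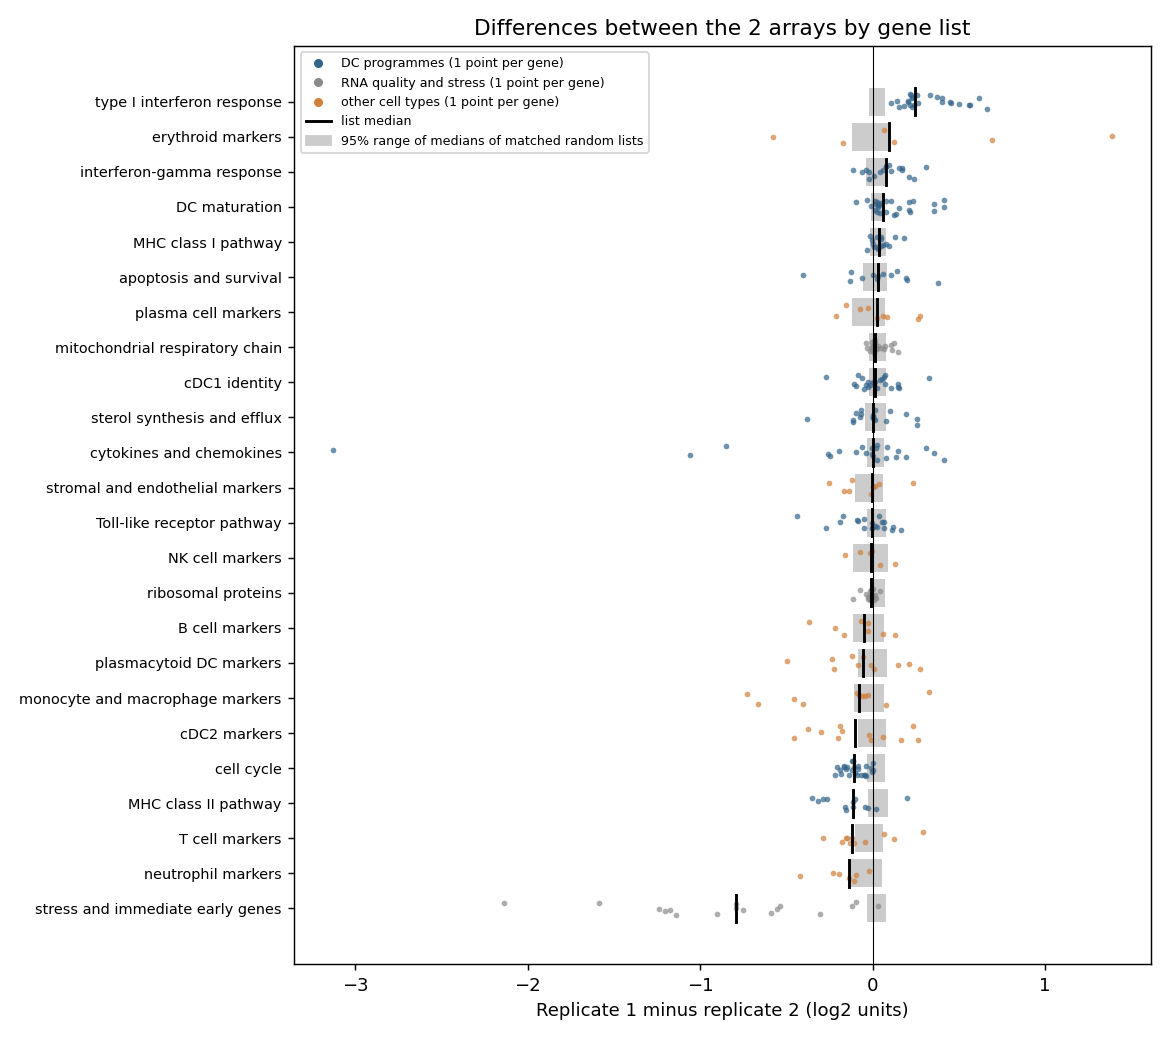
Points give, for each member of a list above background in at least 1 array, the log2 value in replicate 1 minus that in replicate 2, with the list median as a black bar and the 95% range of medians of matched random lists in grey. The stress and immediate early list (median -0.79) and the type I interferon response list (median 0.25) lie furthest from the grey ranges, on opposite sides.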

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

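The lists reduced to members held by no other list were chosen after the data were seen, and put no list on another side of its random range. The number of genes above background was 12281 and ranged from 9297 with the 99th percentile floor to 12467, and each array alone gave 12435 and 12467. All 14 lists of programmes, RNA quality and stress kept counts within 1.5 times of the reported ones under every alternative run; so did the cDC2 and plasmacytoid DC lists, and the other 9 did not. With the 99th percentile floor, the counts above background became 2 for B cell, 4 for plasma cell, 5 for T cell, 2 for NK cell, 4 for monocyte and macrophage, 0 for neutrophil, 2 for erythroid, 2 for platelet and 5 for stromal and endothelial markers, because a higher floor admits fewer dim probe sets. With the floor from other sensory, keratin and defensin genes, B cell and neutrophil markers gave 3 and 2. Taking 1.5-fold as the threshold between replicates gave 20 genes higher in replicate 1 and 59 higher in replicate 2, since a lower threshold admits more. The SD of the replicate difference stayed between 0.139 and 0.157, and all 21 genes that differed by 1 kept their sign under the 4 scaling and probe set alternatives, with 20 or 21 still past 1. No list outside the random range changed sign. The calls of 4 lists depended on the setting, and the cause was not tested: DC maturation moved outside the range with the highest probe set, quantile normalization or unmatched random lists; the interferon-gamma response (median 0.052) and cDC2 markers (-0.072) moved inside it with the loess trend removed; cDC2 markers also did without a filter on dim genes (-0.060); and erythroid markers did with the highest probe set, the loess trend removed or unmatched lists. The list differences cannot be recomputed with a replicate left out, since each needs both arrays. A floor from antigenomic control probe sets was not run, as the tables used here mark none. No paired analysis was possible because there is a single group. Depth has no meaning for these arrays; the floor limits what can be said of genes below about 6 log2 units, for which only a bound is known.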

Other observations

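Tests on the second gene lists were fixed before their values were seen, after the patterns had been; those on marker lists of other cells and on globin scaling were chosen only after the result was seen. The examples named from the second lists were chosen after their values were seen. Of a list of further NF-κB target genes, 18 of 19 were above background, including Icam1, an adhesion molecule for T cells (12.53 ± 0.13, SD, n = 2), and the subunit gene Rel (12.47 ± 0.068), and the list median differed by -0.017 between the arrays (percentile 4.08 of matched random lists). Of a second list of type I interferon response genes, 29 of 29 were above background, including Herc6 (11.87 ± 0.11) and Ube2l6 (11.85 ± 0.11). Of a second list of heat shock genes 16 of 17, and of further immediate early genes 23 of 25, were above background, and of a second erythroid list 18 of 25. Xist was above background in both arrays (12.49 ± 0.048) and the Y-linked genes Eif2s3y, Kdm5d and Uty were not.

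Stress and immediate early genes were higher in replicate 2, and handling before lysis is a candidate explanation that the labels give no way to test. A scaling or intensity-dependent trend left in the values does not account for this: the list median was -0.79 before and -0.80 after the loess trend was removed. The arrays were already normalized, so little trend was left to remove and the test could hardly have come out otherwise. Cells of another type in replicate 2 stay open. The lowest bootstrap bound over the marker lists, that of monocytes and macrophages, was -0.46. This was past the bound of -0.40 set for the test, although no list median reached -0.40. The bootstrap drew list members, which are not replicates and may vary together, and -0.46 equals the difference of Csf1r. The bootstrap bound therefore cannot decide between the explanations. A response shared with other genes of the same kind was only partly seen, since 20 of 24 further immediate early genes were higher in replicate 2 with a median of -0.18 (below all matched random lists), short of the -0.3 set in advance, whereas further heat shock genes went both ways (median 0.080, percentile 97.71, opposite in sign to the stress list, 9 higher in replicate 1 and 7 in replicate 2; Hsph1 -0.73, Chordc1 0.48). The data therefore leave handling, a difference in activation between the samples, and other cells open, and neither handling nor activation was tested. The gate excluded lineage-positive cells.

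Type I interferon response genes were higher in replicate 1 without exception among the 26 measured. A trend left in the values does not account for this, with a median of 0.25 before and 0.21 after the loess trend was removed. Here too the arrays were already normalized and the test had little trend to remove. The second list, whose values had not been seen, gave 0.18 with 26 of 29 genes higher in replicate 1. The difference was therefore shared by further genes of the interferon response. Carry-over of plasmacytoid DC, which the gate for no or low CD317 would largely remove, stays open. Their markers without Bst2 had a median of -0.070 with an upper bootstrap bound of 0.10, both below the cut-off of the test. Of the 10 markers, 3 were higher in replicate 1 and 7 in replicate 2, with an SD of 0.22 over the genes. The rule, written after the data were seen, asked the median to lie below the cut-off by more than this SD. Only a clear shift towards replicate 2 would have met it, so the median does not decide. A difference between the samples in interferon exposure or in timing stays open and was not tested. Ifnb1 was not above background in either array.

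A further difference between the arrays lay outside the gene lists, and was chosen after its values were seen. All 4 probe sets whose listed genes are all globin genes were higher in replicate 1, by 8.49-fold to 10.5-fold (means 12.20 and 8.96). Their median difference was 3.25, and 3.22 less the loess trend. A trend left in the values therefore does not account for it, though in arrays already normalized little trend was left to remove. Red blood cell RNA in replicate 1 is a candidate explanation. The second erythroid list had a median of 0.055 (percentile 99.2, 17 of 19 genes higher in replicate 1), with a bootstrap interval of 0.033 to 0.12. This is below the 0.15 set in advance. Some members lay close to the floor, where differences are understated (for example Epor at 6.18 and Nfe2 at 6.17), so falling short of 0.15 does not decide and the test left it open. The gate excluded lineage-positive cells, and which lineages is not given in the sources used here. In the first list, 4 of the 6 genes above background in at least 1 array were higher in replicate 1 and 2 in replicate 2. Alas2 differed by at least 1.23 (below background in replicate 2), Slc4a1 by 0.69, Tspan33 by 0.066 and Klf1, at the floor, by 0.12. Car1 and Car2 differed by -0.58 and -0.17.

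Among the other probe sets naming several genes, 3 of mostly immunoglobulin genes were higher by at least 1 log2 unit in replicate 1 and 3 in replicate 2, 4 of small nuclear or nucleolar RNA genes in replicate 2, and 1 of heat shock genes in replicate 2 (-1.11). Of the 12146 probe sets unnamed here, 57 were higher by at least 1 in replicate 1 and 20 in replicate 2.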
